A study of Methylorubrum extorquens PA1 with 6 samples.

How the data were processed

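RNA was sequenced from 6 samples of the methylotrophic bacterium Methylorubrum extorquens PA1: 3 samples of the wild type (strain CM2730) and 3 of a strain that lacks the gene ttmR (strain CM4732). Per the labels, the cells grew at 30 °C in a PIPES-buffered medium with 15 mM methanol as the carbon source and were in early exponential phase. Total RNA was taken with an RNeasy column kit, ribosomal RNA was removed with a Ribo-Zero kit, and the remaining RNA was fragmented, copied into cDNA and amplified with a limited number of PCR cycles, per the labels' protocols. Samples were grouped by the genotype label, and the replicate numbers 1 to 3 are those of the sample titles. The titles of the deletion samples read marR where their count columns read ttmR. These were matched by the genotype label and the replicate number. Nothing in the labels says whether the 3 samples of a strain came from separate cultures, so the p-values measure the spread between these samples, which may be technical.

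The authors deposited raw read counts per locus tag for all 6 samples. The submitters' processing notes name FastQC, Trimmomatic, HISAT2, Cufflinks, featureCounts and DESeq2, without parameters or order. The genome build, the annotation, the strand setting of the counting and the treatment of reads that match several places are not given in the sources used here. Reads from overlapping or near-identical genes could therefore not be told apart, and a high count at a tag next to a strongly expressed one can include some of its reads. The authors also deposited a table of their own comparison, with log2 fold changes and their standard errors, p-values and adjusted p-values, and a signal per ID, the mean of the counts after division by size factors, per the file headers. A further pair of deposited tables held subsets of it; they were checked to be the 945 IDs with an adjusted p under 0.05 and the 76 of these with an absolute log2 fold change above 1. Fitting DESeq2 to the same 6 count columns, without the 75 IDs that carry the letter R before their number, gave the authors' log2 fold changes with a median absolute difference of 1.5e-15 over 4804 IDs and the same number of calls, 945.

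The count table listed 4904 IDs, of which 4829 had the form Mext_ and a number and 75 carried the letter R. It gave no gene symbol, product, coordinate or strand. The gene table at hand describes another strain, DM4, and none of its entries carries a Mext_ tag, so 0 of 4904 IDs could be matched to a name. The 24 gene lists fixed before the data were examined (methanol oxidation, formaldehyde oxidation, serine cycle, stress responses, transport and others) could therefore not be applied, and neither the counts per list nor the set tests were run. For the same reason no gene function is given, and a maximum of 2 IDs that rose and 2 that fell are named. The rule for named genes, also fixed before the data were examined, took the IDs with the largest absolute log2 fold change among those with an adjusted p under 0.05, a mean of at least 5 CPM (read counts scaled to a common library size, in the usual CPM unit) and no overlap between the groups. It was to take 10 IDs in each direction, and its list was shortened to the limit above. It gave the first risen ID and both fallen ones. The second risen ID is the one with the largest change in the next longest run of adjacent tags and was chosen after its values were seen. The design also foresaw that ttmR would be identified from the counts if no table named it, and this was done. Locus tag numbers were taken as the order of the genes, which is the usual convention; coordinates were not used here.

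Differences between the strains were tested with edgeR's quasi-likelihood test (edgeR 4.0.16 in R 4.3.3; TMM scaling, edgeR's default filter on low counts, robust fit), with Benjamini-Hochberg adjusted p under 0.05 as the threshold. The filter kept 4856 IDs, 53 of them with the letter R, and removed 48. CPM were computed with the TMM-scaled library sizes. The standard error of a log2 fold change was its size divided by the square root of the test's F value. A run was a set of at least 3 consecutive locus tag numbers called in the same direction, and the number of runs was compared with 1000 shuffles of the calls over the tested tags. Alternatives were other scalings, other filters, DESeq2 1.42.0, limma 3.58.1 with voom weights, a fit without robust estimation, a block for the replicate number, leaving out each sample in turn, and leaving out the IDs with the letter R. After the data were seen, DESeq2 without those IDs, thinning to equal depth, removal of a trend with expression level and another definition of adjacency were added.

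The libraries held 2509660 to 5085047 counts. A count of 0 in a library allows a level of up to 3 counts, which is 0.59 to 1.2 CPM in these libraries. This range was computed with the library totals, without TMM scaling. Confidence intervals on shares of counts are 95% Wilson intervals; they cover counting error only, since PCR copies were not distinguished. The procedure was tested on simulated data, with 4856 simulated IDs of this comparison and 200 changed. edgeR recovered 18% of the changes of 1.2-fold, 78% of those of 1.5-fold, 98% of those of 2-fold and 100% of those of 4-fold. Of its calls, 3.3% were false. The simulation gave IDs of like level the same spread. It held no trend with level that differed between libraries and no outlying library, so this share may not hold for the real calls. Pairs of libraries of 1 strain differed by more than counting noise, with chi-square values of 3.27 to 16.4 per degree of freedom, so no pair was taken as repeat deposits of 1 library; this does not show that they came from separate cultures.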

Results

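The transcriptome of Methylorubrum extorquens PA1, a bacterium that can live on methanol and oxidises it by way of the toxic intermediate formaldehyde, was compared between the wild type and a mutant without ttmR, 1 of 2 genes whose products the study describes as responding to formaldehyde. Both strains grew on 15 mM methanol, and 3 samples of each were sequenced in early exponential phase. The wild-type libraries held 3636133, 3440100 and 5085047 counts and the deletion libraries 2509660, 3509555 and 4161688. On the log2 scale, wild-type libraries correlated with one another at Pearson's r of 0.989 to 0.992 across IDs and deletion libraries at 0.980 to 0.992, while libraries of different strains correlated at 0.956 to 0.972; IDs are not independent replicates. Deletion library 1 stood apart from the other deletion libraries, with r of 0.980 and 0.981 against 0.992 between those. The first principal component, with 60.9% of the variance, separated the strains. On the second, with 19.0%, deletion library 1 lay at -13.4 and the other deletion libraries at 8.80 and 7.02. The correlations and components cover all tested IDs, among them the 53 with the letter R. Deletion library 1 held far more reads at a few of those. How much of its distance comes from them was not tested. The spread between replicates, as the common biological coefficient of variation, was 10.1%.

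The first question was which gene the deletion removed. Transcripts of Mext_0925 fell from 981 ± 175 CPM in the wild type to 1.33 ± 0.87 CPM in the deletion strain (SD, n = 3 each). The wild-type libraries held 3479, 3774 and 4008 reads of it and the deletion libraries 6, 2 and 5. Summed over libraries, the level was 769-fold lower, with an exact interval of 450 to 1446-fold that covers counting error only. The log2 fold change was -9.58 ± 0.35 (SE), with an adjusted p of 3.4e-05 in edgeR's quasi-likelihood test. No other ID came close: among the 1924 IDs above 100 CPM in the wild type, the next lowest ratio of deletion to wild type was 22%. The count table does not pair IDs with gene names, so that this ID is ttmR rests on the counts and not on an annotation.

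Transcripts of the genes on either side of Mext_0925 were not called different. The tag just before it was at 2824 ± 113 CPM in the wild type and 2892 ± 207 in the deletion strain (SD, n = 3), a log2 fold change of 0.03 ± 0.07 (SE) with an edgeR adjusted p of 0.756. The tag just after it was at 73.0 ± 5.8 and 73.3 ± 3.1 CPM, a log2 fold change of 0.01 ± 0.09 with an adjusted p of 0.975. The tags next to these had log2 fold changes of -0.09 ± 0.07 and 0.12 ± 0.11 and adjusted p of 0.365 and 0.458. A trend with expression level was also removed from each library, an alternative chosen after seeing the data. The tag just before Mext_0925 was then called higher by edgeR, at a log2 fold change of 0.37. In the highest of 3 equal classes of level the median log2 fold change was -0.09, so this removal raises values at high levels. Whether that accounts for the whole shift of the tag was not tested.

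**Figure D1:**
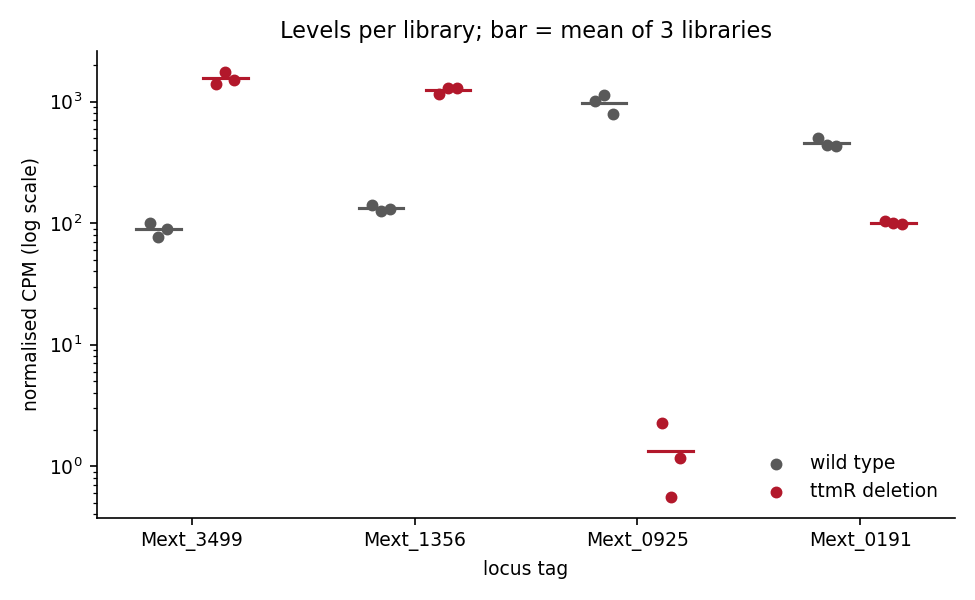
Normalised CPM (log axis) of the 4 named locus tags in each of the 3 wild-type (grey) and 3 deletion (red) libraries; bars are group means. Mext_3499 and Mext_1356 lie higher in all 3 deletion libraries, Mext_0191 lies lower, and Mext_0925 lies at 2.27 CPM or less in each of them.

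The main comparison asked which other transcripts differ between the strains during growth on methanol. Large changes were mostly rises: 63 IDs rose and 15 fell by more than 2-fold, and 33 rose and 4 fell by more than 2 on the log2 scale. Among the IDs that met the rule for named genes, the largest rise was that of Mext_3499, from 88.8 ± 11.4 to 1548 ± 183 CPM (SD, n = 3). This was a 17.4-fold change (log2 4.12 ± 0.10 SE, edgeR adjusted p = 7.3e-20). Mext_1356 rose from 132 ± 7.3 to 1242 ± 85.2 CPM, a 9.39-fold change (log2 3.23 ± 0.08, adjusted p = 7.5e-27). Next to Mext_0925, the largest fall by the same rule was that of Mext_0191, from 457 ± 36.4 to 101 ± 2.6 CPM. This was a 4.54-fold change (log2 -2.18 ± 0.07, edgeR adjusted p = 4.4e-23). Each of these differed in the same direction in 3 of 3 deletion libraries against every wild-type library, which the rule for named genes required of all but Mext_1356. The adjusted p-values are from edgeR's quasi-likelihood test.

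The IDs that rose by more than 2-fold took 0.770% ± 0.028 of all counts in the wild type and 5.56% ± 0.26 in the deletion strain (SD, n = 3). Those that fell by more than 2-fold, Mext_0925 among them, took 2.71% ± 0.06 and 0.849% ± 0.098. In the wild type the risen IDs had a median level of 79.99 CPM, near the 73.0 CPM of all tested IDs, and the fallen ones a median of 427 CPM.

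Most of the IDs that rose strongly lay side by side. A run of 13 consecutive locus tags, of which Mext_3499 is the second, rose together with a median log2 fold change of 3.05; its summed level went from 2528 ± 157 to 22864 ± 1854 CPM (SD, n = 3), a 9.04-fold change. A run of 10 tags, of which Mext_1356 is the second, rose with a median of 2.79, from 2790 ± 205 to 18605 ± 1066 CPM, a 6.67-fold change. A run of 6 tags rose with a median of 2.78, from 628 ± 27.7 to 4158 ± 286 CPM, a 6.62-fold change. These 3 runs, which are those with the largest median changes, hold 29 tags and 25 of the 33 IDs that rose by more than 2 on the log2 scale. Together they took 0.575% ± 0.029 of the counts in the wild type and 4.71% ± 0.24 in the deletion strain. This share was higher in each of the 3 deletion libraries than in any wild-type library, which choosing the runs by their change favours. With 3 libraries against 3, an exact permutation test cannot go below 0.1.

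**Figure D2:**
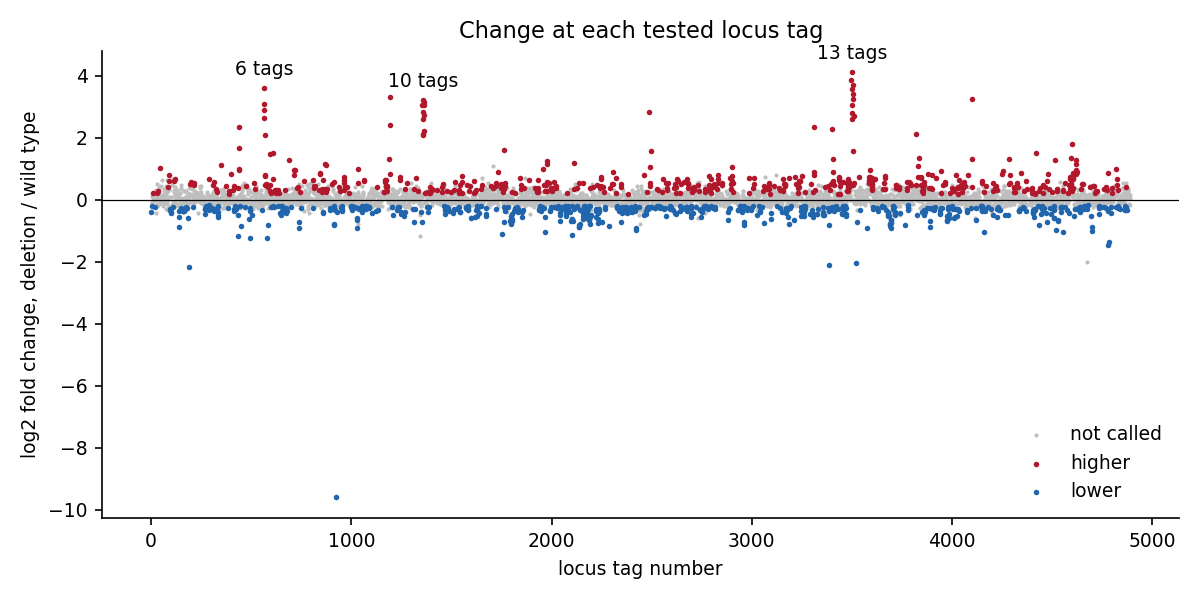
Log2 fold change (deletion against wild type) of each tested locus tag without the letter R against its tag number; red, called higher; blue, called lower; grey, not called. The runs of 13, 10 and 6 tags hold 25 of the 33 IDs above 2, other red points reach similar heights, and the single point near -9.58 is Mext_0925.

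The tags within a run did not all rise equally. In the run of 10, the log2 fold changes lay between 2.09 and 3.23. In the run of 13, 11 tags rose by more than 2-fold, while the tenth and the thirteenth rose by 0.48 ± 0.07 and 0.53 ± 0.11 (SE) on the log2 scale. In the run of 6, the last tag rose by 0.49 ± 0.07 and the other 5 by 2.08 to 3.61. The run of 13 was flanked by tags with log2 fold changes of 0.36 before it and -0.02 after it, neither called. The tag before the run of 10 fell, with a log2 fold change of -0.71 ± 0.17 and an edgeR adjusted p of 0.002.

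**Figure D3:**
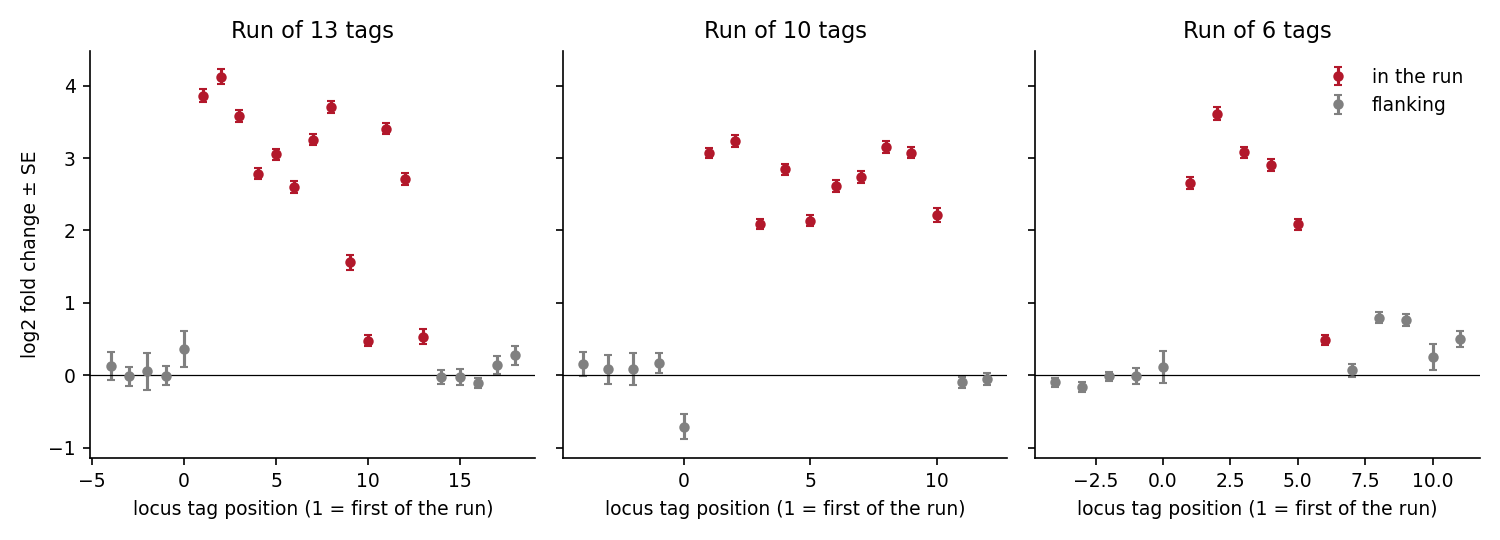
Log2 fold change with its standard error at each tag of the 3 runs (red) and at tested tags within 5 positions on either side (grey), from 3 libraries per strain. The rise starts within 1 tag at the front of each run; the grey tag just before the run of 10 was called lower, and 3 grey tags after the run of 6 were called higher.

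Smaller changes were numerous and went both ways. In all, 1194 of 4856 tested IDs (24.6%) had an adjusted p under 0.05 in edgeR's quasi-likelihood test, 543 higher and 651 lower in the deletion strain, and the median absolute log2 fold change among them was 0.38. Under 2-fold there were 1116 calls, 480 higher and 636 lower. The libraries of the strains did not overlap for 1129 of the 1194 calls, which being called favours. They did not overlap for 37.7% of all tested IDs, where chance gives 10% on average. Since IDs are not independent, effects shared by whole libraries could add to this share. Scaling by library totals alone moved the split to 857 higher and 380 lower (69.3% higher, against 45.5%). This scaling shifts the median log2 fold change of all tested IDs from 0.02 to 0.11. Removing the trend with expression level, an alternative chosen after seeing the data, gave 1068 calls, 582 higher and 486 lower (54.5% higher). Which direction had more calls therefore depended on the processing.

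The direction of the smaller changes went with the expression level. Among calls under 2-fold, when the tested IDs were divided into 3 classes of equal size by level, 9.7% were lower in the deletion strain in the lowest class, 41.3% in the middle one and 80.2% in the highest one. The lower calls under 2-fold took 42.4% ± 0.39 of the counts in the wild type and 34.3% ± 0.93 in the deletion strain (SD, n = 3), and the higher ones 4.46% ± 0.07 and 6.33% ± 0.08. With the trend with level removed, an alternative chosen after seeing the data, 68.2% of the calls under 2-fold were still made in the same direction.

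**Figure D4:**
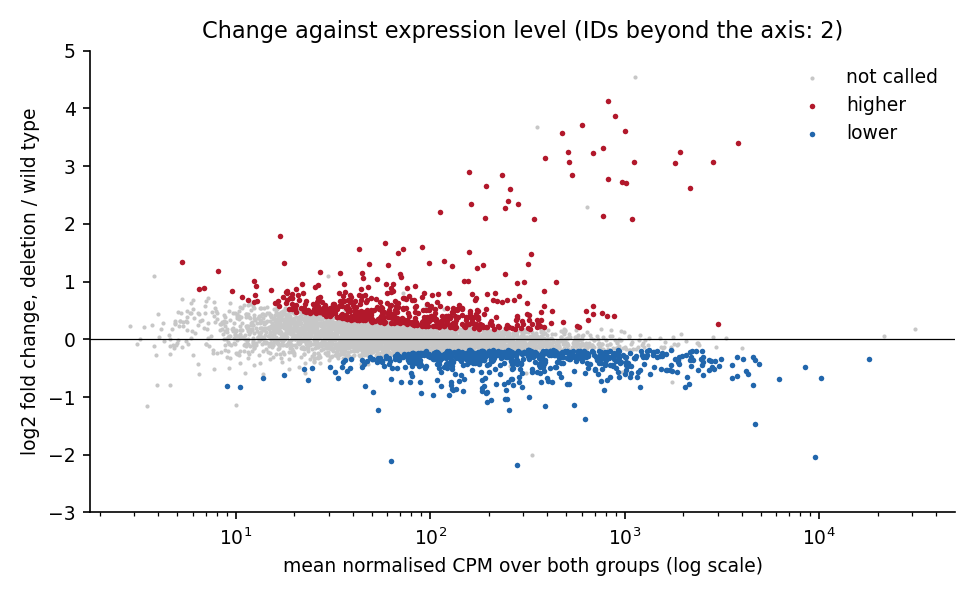
Log2 fold change of each tested ID against its mean normalised CPM over both strains (log axis); red, called higher; blue, called lower; grey, not called, and 2 IDs lie beyond the axis. Lower calls lie mostly to the right, at high levels, and most red points above 2 belong to the 3 runs; the grey points above 2 are IDs with the letter R.

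Adjacent tags were called together across the genome. There were 101 runs of 3 or more consecutive tags called in the same direction, 41 higher and 60 lower, which held 415 calls (34.8% of all). Shuffled calls gave a median of 16 runs and at most 27 in 1000 shuffles. Of the 27 runs of 5 or more tags, 10 were higher and 17 lower, and the longest lower run had 9 tags. All 7 runs whose median change exceeded 2-fold were higher in the deletion strain. The shuffles did not keep expression level. Removing the trend with level left 66 runs, which were not compared with shuffles.

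In the authors' deposited table, 945 IDs had an adjusted p under 0.05, 380 higher and 565 lower, and 76 of them an absolute log2 fold change above 1. Of the 945, 929 were also called by edgeR here, each in the same direction, and 16 were not. A further 258 IDs of that table, and 7 IDs with the letter R, were called by edgeR alone. Above 2-fold, all 76 calls of the authors' deposited table were shared, and edgeR added 2. For Mext_3499 the authors' deposited table gives a log2 fold change of 4.12, for Mext_1356 3.23, for Mext_0191 -2.19 and for Mext_0925 -9.62.

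The 75 IDs with the letter R, which the authors' deposited table leaves out, took 2.43% to 3.42% of the counts in the wild-type libraries and 5.14%, 3.70% and 3.55% in deletion libraries 1, 2 and 3. One of these IDs held most of them, at 2.26% to 3.11% of all counts in the wild type and 3.35% to 3.50% in the deletion strain, and was not called different (log2 fold change 0.19, edgeR adjusted p = 0.503). Of the 53 tested, 6 rose and 1 fell. Apart from the most abundant one, they took 1.69% of the counts in deletion library 1 (95% Wilson interval 1.67% to 1.70%), against 0.170% to 0.307% in the other 5 libraries. Without deletion library 1, 1012 IDs were called different, 439 higher and 573 lower, and all 29 tags of the 3 runs were still called higher.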

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

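The alternatives with the trend with expression level removed, with equal depth, with DESeq2 without the IDs that carry the letter R and with adjacency among tested IDs (103 runs) were chosen after seeing the data. Mext_0925, Mext_0191, Mext_3499 and Mext_1356 kept their direction and stayed called under each alternative run. Leaving out 1 library gave 869 (without wild-type library 1) to 1200 (without wild-type library 3) called IDs against 1194, 77 to 88 above 2-fold against 78, 68 to 95 runs against 101, and a log2 fold change of Mext_0925 of -10.05 to -9.23. DESeq2 called 939 IDs, limma with voom weights 1122, DESeq2's size factors in edgeR 1195, the upper quartile 1137, no filter 1189 and equal depth 1070. Scaling by library totals gave 857 higher and 380 lower calls, as its shift of all IDs implies. With the trend with level removed, 582 of the 1068 calls were higher and 486 lower. Counting runs of at least 2 tags gave 242, by construction. Removing the trend with level gave 66 runs and called the tag just before Mext_0925 higher (log2 fold change 0.37). That tag had a high level, 2824 CPM in the wild type. In the highest of 3 equal classes of level the median log2 fold change was -0.09, so removing the trend raises values there. Whether this accounts for the whole shift of the tag was not tested. Requiring more than 2-fold in both left 76 calls shared with the authors' deposited table, by construction. Whether the replicate numbers pair the samples stays open. Same-numbered libraries deviated from their group means with correlations of -0.38, -0.11 and 0.25, which are too few to decide. A replicate block gave 1346 calls against 1194. Gene list counts and set tests were not run, since no ID could be matched to a name. In simulated data with 200 of 4856 IDs changed, 18% of changes of 1.2-fold were recovered, so small changes can be missed. The real comparison gave 1194 calls, many more than the changes simulated, so this share may not carry over to it.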

Other observations

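The splits of the samples, the shuffles without 1 library and the tests at IDs with the letter R, at equal depth and with the trend with level removed were chosen after results were seen; the shuffles of all calls were planned, but the outcome they were held against was written down after they were seen. The real split of the 6 samples gave 1194 edgeR calls, and 1 of the 10 splits gave as many, the real one. The highest of the others gave 0, with 41 to 388 IDs at an unadjusted p under 0.05 against 1701; no other tool was run on them. Each of the other splits mixes the strains in both groups, where a real difference between strains adds to the spread and lowers the calls. With 10 splits the share cannot fall below 0.1, so they are too few for a share under 0.05.

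Of the 1116 calls under 2-fold, which went mostly down at high levels and up at low ones, 98.3% were made in the same direction with DESeq2's size factors, 92.1% with the upper quartile and 75.6% with library totals, and 0 in the opposite one under these scalings; the share under library totals missed the bound of 80% set beforehand, so scaling stays open for part of them. A difference in depth between libraries is argued against by thinning to equal depth, after which 100% kept their direction; since thinned counts are part of the full ones this is a lenient measure, and 82.7% were still called, of 1070 calls in all. A bias that depends on level stays open: 80.2% of these calls were lower in the highest of 3 equal classes of level, and after removal of the trend 68.2% were still called in the same direction and 4 in the opposite one. The trend between strains (-0.25 in median log2 change, highest against lowest class) exceeded the 0.227 of the widest pair of libraries of 1 strain, which met the bound set beforehand; the bound had no margin for spread, and a requirement that the strains not overlap was added after the value was seen. The libraries of the strains overlap in this trend. An exact permutation test of it gave p = 0.2, where 3 against 3 cannot go below 0.1. Whether the trend comes from the genotype or from the libraries therefore stays open.

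Calls lay side by side more often than when shuffled over the tags, in 101 runs against at most 27 in 1000 shuffles. The shuffles did not keep expression level, with which the direction of the smaller changes went. They therefore cannot tell how much the trend with level adds to the runs. The runs left after removing that trend were not compared with shuffles. A single library is argued against as the cause: leaving out each in turn gave 68 (without wild-type library 1) to 95 runs, where shuffles of the calls made without it gave at most 30. All 29 tags of the 3 runs with the largest median changes were called higher without any 1 library. A hypothesis is that the tags of a run may be transcribed together, which coordinates and strand would be needed to test. Reads counted at a neighbouring gene stay open for the same reason. The tenth tag of the run of 13 nevertheless rose by only 0.48 on the log2 scale, between tags that rose by 1.56 and 3.41. Transcription together does not by itself account for so small a rise within the run.

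Deletion library 1 held more reads than the other 5 libraries at IDs with the letter R apart from the most abundant one. Whether the genotype has a part in this stays open: 1 of the 3 deletion libraries lay above the wild-type range in the share of counts at these IDs, but that is the pattern itself and decides nothing. A like rise of all these IDs is argued against as the source of the whole excess. The median ratio of that library to deletion libraries 2 and 3 was 1.29 over 52 IDs, where their summed share of counts had a ratio of 8.41. Since the median lies above 1, a smaller general rise stays open. Of the 42296 reads, 33895 (80.1%) came from 4 IDs, which held 3348 reads in wild-type library 2 and 89 to 455 in the other 4 libraries. What these IDs encode is not given in the sources used here, and incomplete removal of a few abundant RNAs may be a source that was not tested.

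One ID without the letter R had 4529 reads in wild-type library 1 and 386 to 691 in the other 5 libraries, and was not called different.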
